A study of Mus musculus with 5 samples.

How the data were processed

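The data were bulk RNA-seq of lung airway tissue, with trachea and lung, of mouse embryos at E13.5, from 2 samples with Prmt5 deleted in the epithelium and 3 control samples. Groups and replicate numbers were taken from the genotype labels and titles. The labels call the mutants a knockdown, while the design text and growth protocol describe an epithelial knockout. They are called mutants here. The design text also names Shh with Prmt5 in the mutant genotype. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were made from 1.3 ug of total RNA with a SMARTER mRNA-Seq kit.

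The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled by the reads of the library) for 19699 gene entries and 5 libraries, and the unit is per the name of the deposited table. The submitters' processing notes name the GRCm38 (mm10) genome build. The aligner, the read counter, the annotation, the filters and the use of strand are not given in the sources used here, so overlapping, antisense and near-identical genes cannot be told apart where their reads were shared. The values were not whole and summed to different totals per library. In 100% of the entries the 5 values were whole multiples of what 1 read is worth, at a relative tolerance of 1e-13 and up to a factor shared by the libraries. Gene lengths from these steps equalled the summed exon length in GENCODE M21 (GRCm38) exactly for 13961 of 18885 genes with 1 symbol match (73.9%), and the annotation settled the shared factor for 870 genes. This gave the reads of each gene and the reads in the denominator of each library, 15652503 to 18682463, of which 97.2% to 97.4% lay in listed genes. Gene positions were taken from the same annotation by symbol. No column was without a sample. A floor of 3 reads over a group was used for genes with 0 reads in a group, and it covers counting error only.

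The test was limma (lmFit, then eBayes with a trend, two-sided) on log2(FPKM + 1) of the FPKM as deposited, with no covariate and all 5 libraries. Genes were kept at 1 FPKM or more in at least 2 libraries, 12838 in all, and p-values were adjusted by Benjamini and Hochberg's method over these genes, with a threshold of 0.05. The 2 against 3 design allows an exact permutation p of 0.1 at best, so a test of single values cannot pass. The main test used no count model, since it was set for FPKM values before the reads were recovered. Voom on the recovered reads was added later as an alternative. Of 28 gene lists with 462 symbols, 450 were found in the table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, with camera at an estimated correlation and fry beside it, and counts of members are given over all genes and adjusted over the list alone. Camera compares a list with the other genes, and fry's directional test asks whether a list's genes move one way on balance. Mymk of the muscle list is in the table under its older symbol Tmem8c and was not counted as a member.

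The design, the lists, the alternatives listed first below and the rule for named genes were fixed before the data were examined. The rule names Prmt5, then the 15 largest rises and 15 largest falls among genes past the threshold with groups that do not overlap and a mean of at least 1 FPKM in either group. It leaves out predicted genes, genes with no symbol, pseudogenes and sex-linked genes. It adds the 4 members of each list described with the smallest p, and 16 genes given whatever they show: Bmp4, Id1, Id3, Cdkn1a, Mdm2, Ccng1, Epcam, Cdh1, Nkx2-1, Shh, Sox2, Sox9, Trp63, Foxj1, Sftpc and Scgb3a2. Of the genes of the rule, 1 is not reported here and stays in the counts. Gm23935, Lars2, Rn18s-rs5, Ddx3y, Xist, Myl7, Xpc, Btg2, Ddb2, Bax, Cyp2f2, Mcidas, Gmnc, Ak7, Drc1, Calca, Chga, Chgb, Spry1, Spry2, Spry4, Spred3, Etv5 and further p53 targets are named in the report outside that rule, chosen after their values were seen.

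The steps were tested on simulated reads for the same 12838 genes and library sizes, with 200 genes changed in each of 5 runs at a dispersion of 0.02. The test recovered 6.27% of the genes changed 1.5-fold, 65.1% of those changed 2-fold and 96.1% of those changed 4-fold. Of its calls 14.2% fell on unchanged genes, 87 of 92 of them with a mean under 50 reads, and 0.923% where the mean was 50 or more. Voom made 4.12% of its calls on unchanged genes. The dispersion was 1 set value for all genes and was not estimated from the data. Some genes varied far more, such as Scgb3a2 with controls at 39.8 ± 31.0 FPKM (SD, n = 3). The shares recovered and falsely called may thus not hold for these data. A list that was moved was called in 5 of 5 runs and other lists in 0. The simulated genes varied independently of each other, so this does not test list calls where members vary together. In the data the estimated correlation was 0.136 within the p53 list and 0.825 within the secretory list. Of the 303 genes called in the data, 39 had a mean under 50 reads.

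Alternatives set beforehand were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, median ratio scaling, quantile normalization, TPM, limma without a trend or with robust fitting, the replicate number as a block, each library left out in turn and a change of at least 1 on the log2 scale. Alternatives added after the data were seen were voom on the recovered reads, a mean of at least 50 reads, TPM without Gm23935, the male share of each library as a covariate and removal of each library's trend on gene length. The male share was the mean level of the Y-linked genes relative to the mutant mean. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The treatment protocol in the labels describes the adipogenic differentiation of cultured cells, which is at odds with the embryonic tissue named in the other labels, and was not used.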

Results

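RNA was sequenced from the main airway section, with trachea and lung, of mouse embryos at the embryonic stage E13.5. The mutants lacked Prmt5, an enzyme that adds symmetric dimethyl groups to arginines of histones and splicing proteins, in the lung epithelium, and littermates were the controls. There were 2 mutant and 3 control libraries, each numbered as a separate sample, with 1 FPKM value per gene and library. Nothing in the labels says whether a library held 1 embryo or several, so the p-values measure the spread between these libraries, which may be technical in part. The reads behind each library were recovered from the steps between FPKM values. They came to 15756526 and 15652503 in mutant replicates 1 and 2, and to 18682463, 16305922 and 18219269 in control replicates 1, 2 and 3. Xist, the RNA of the inactive X chromosome of females, was at 0.0673 and 0.289 FPKM in the mutants and at 57.3, 58.1 and 115 FPKM in the controls. The Y-linked Ddx3y was at 12.0 and 10.8 FPKM in the mutants and at 9.91, 6.70 and 2.54 FPKM in the controls. All 3 controls thus held RNA of both sexes in different shares, and so of more than 1 embryo. The mutants looked male, and whether each held 1 embryo or several cannot be told. Sex make-up thus differed with genotype and cannot be separated from it in full. Gm23935, an annotated microRNA gene of 57 bases, took 0.143% to 3.35% of the reads but 7.69% to 64.8% of the summed FPKM of a library. The entries Lars2 and Rn18s-rs5 also differed widely between libraries, from 174 to 3563 FPKM and from 435 to 7739 FPKM, and the cause was not tested.

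Prmt5 itself (chromosome 14, 54507187 to 54517525, GRCm38) was at 23.7 and 20.1 FPKM in the mutants, from 1480 and 1247 reads. The controls were at 28.7, 26.4 and 25.8 FPKM, from 2121, 1706 and 1858 reads. Both mutants lay below all 3 controls, and the mutant mean was 18.7% lower. The log2 change was -0.29 (SE 0.12), which did not pass with limma (adjusted p = 0.234). The exact permutation test of the FPKM values, two-sided, gave p = 0.1, the smallest that the 10 splits of 5 libraries allow. Whole tissue holds mesenchyme that keeps the gene, and a value per gene also counts reads outside any deleted exons, so Prmt5 checks the labels only in part.

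The comparison of mutant with control asked which genes change when the airway epithelium loses Prmt5, a loss after which, per the design text, ciliated cells are missing. The mutants had more RNA of most p53 target genes tested, of some distal lung genes and of some homeobox genes, and less RNA of some conducting airway genes and of most skeletal muscle genes tested. With limma, 303 of 12838 genes passed an adjusted p of 0.05, of which 127 were higher and 176 lower in the mutants. An unadjusted p under 0.05 was reached by 2421 genes, 838 higher and 1583 lower. Of the 15 largest rises by the naming rule, Pmaip1, Cdkn1a and Gdf15 are given with the p53 targets. The largest was that of Calb2, which encodes the calcium-binding protein calretinin, at 26.6 ± 3.37 (SD, n = 2) against 2.76 ± 1.5 FPKM (SD, n = 3; log2 change 2.95, SE 0.29, adjusted p = 0.00691). Cldn18, a tight junction gene of lung and stomach epithelium, was 7.16-fold higher, and Pthlh, which encodes a parathyroid hormone-like peptide, 4.89-fold higher (adjusted p = 0.0419 and 0.00758). The controls of Cldn18 varied widely, at 3.70, 8.13 and 1.11 FPKM. Among homeobox genes, Hoxb8 was 11.1-fold, Hoxb6 5.05-fold and Nkx2-9 23.2-fold higher (adjusted p = 0.00795, 0.0312 and 0.00641). The controls of Hoxb8 were low, at 0.488, 0.978 and 0.146 FPKM. Hoxb8 and Hoxb6 lost the threshold with no filter and with the male share as a covariate. Nkx2-6 had 140 reads in the mutants and 0 in the controls, at least 79.1-fold higher against a floor of 3 reads over the group. Krt23, Sec14l5, Rgs14, Ddit4l and Ltb4r2 completed the 15 named rises, with log2 changes of 1.81 to 1.99.

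Of the 15 largest falls, 9 were genes of skeletal muscle, described with that tissue. Sox2, a transcription factor of the conducting airway and oesophagus, fell from 29.2 ± 14.0 (SD, n = 3) to 3.43 ± 0.947 FPKM (SD, n = 2; log2 change -2.68, SE 0.36, adjusted p = 0.0163). Aldh1a7, Cckar, Cldn10 and Il17b fell by 2.39, 2.71, 2.24 and 2.14 on the log2 scale (adjusted p = 0.0077, 0.0115, 0.00644 and 0.00758). Kcnk16, a potassium channel gene, had 187 reads in the controls and 0 in the mutants, at least 36.8-fold lower. All log2 changes are on the scale of log2(FPKM + 1), which understates the change of low genes.

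All 303 genes had groups that did not overlap. This held for 37.6% of the genes tested, where chance gives 20%. Median ratio scaling, which gave 148 higher and 147 lower genes, and quantile normalization, which gave 133 and 115, evened out the split. Conversion to TPM, which divides by totals of which Gm23935 took 7.69% to 64.8%, moved the median log2 change of all genes from -0.06 to -0.59 and left 10 higher and 57 lower genes. TPM without that gene gave 112 higher and 277 lower. Without mutant replicate 1 the count was 4 and without mutant replicate 2 it was 11, with the lone mutant assumed to vary like the controls. Of the 63 genes of the naming rule past the threshold, 61 and 56 lost it in those fits, at adjusted p of 0.0575 to 0.224 and 0.0541 to 0.361. Without control replicate 1, 2 or 3 the losses were 8, 15 and 14 of the 63. They concerned 21 genes, at adjusted p of 0.0509 to 0.0885. Control replicate 1 mattered for Cldn18, Myl1, Tppp3, Lfng, Col9a3, Dbh, Tubb3 and Chrd. Control replicate 2 mattered for Myl1, Mdm2, Shh, Tppp3, Muc1, Nov, Napsa, Dusp6, Lfng, Col9a3, Dbh, Foxa1, Ngfr, Chrd and Twist1. Control replicate 3 mattered for Myl1, Mdm2, Nov, Napsa, Dusp6, Lfng, Col11a1, Ret, Dbh, Tubb3, Ngfr, Chrd, Tbx4 and Wnt2. Of the settings that kept all libraries, 10 of 15 ended the call of Wnt2 and 9 of 15 that of Cldn18. Nov and Tubb3 lost it in 8 of 14 and 8 of 15, Foxa1, Myl1 and Tppp3 in 7 of 15, Dbh and Muc1 in 6 of 14, and Shh and Twist1 in 6 of 15. The count was 69 with no filter on low values and 94 with the male share of each library as a covariate. It was 600 with voom on the recovered reads and 592 among genes with a mean of at least 50 reads.

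Most p53 target genes tested rose in the mutants. Of 30 tested, 18 passed over all genes and all 18 were higher, and 23 passed adjusted over the list alone. With the male share as a covariate 6 of the 18 stayed past the threshold. Pmaip1, which encodes the pro-apoptotic protein Noxa, went from 0.575 ± 0.0238 (SD, n = 3) to 10.2 ± 0.275 FPKM (SD, n = 2; log2 change 2.83, SE 0.13, adjusted p = 0.000667). Cdkn1a, which encodes the cell cycle inhibitor p21, went from 11.5 ± 1.80 (SD, n = 3) to 45.7 ± 4.63 FPKM (SD, n = 2; log2 change 1.91, SE 0.15, adjusted p = 0.00618). Ccng1, a cyclin G gene, was 2.67-fold, Epha2, an ephrin receptor gene, 3.41-fold and Mdm2, which encodes the ubiquitin ligase of p53, 1.71-fold higher (adjusted p = 0.00641, 0.00644 and 0.0292). Gdf15 was at 3.11 FPKM in the mutants, with 181 reads against 6 in the controls (adjusted p = 0.0175). Eda2r, Fas, Sesn2, Phlda3 and Bbc3 had log2 changes of 1.65, 1.36, 1.19, 1.10 and 1.04. Rps27l was also past the threshold, at 0.91, but shares sequence with Rps27 and its copies, so its level is less certain. Not past the threshold were Bax, at a log2 change of 0.82 (adjusted p = 0.0605), and Btg2, Ddb2 and Xpc, at -0.12, -0.35 and -0.07. The list was higher by camera with its preset correlation (adjusted p = 5.96e-25 over 28 lists), but not with an estimated correlation, where the p was 0.0121 and the adjusted p = 0.34. It was the 1 list that passed fry's directional test (adjusted p = 0.0174).

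**Figure D1:**
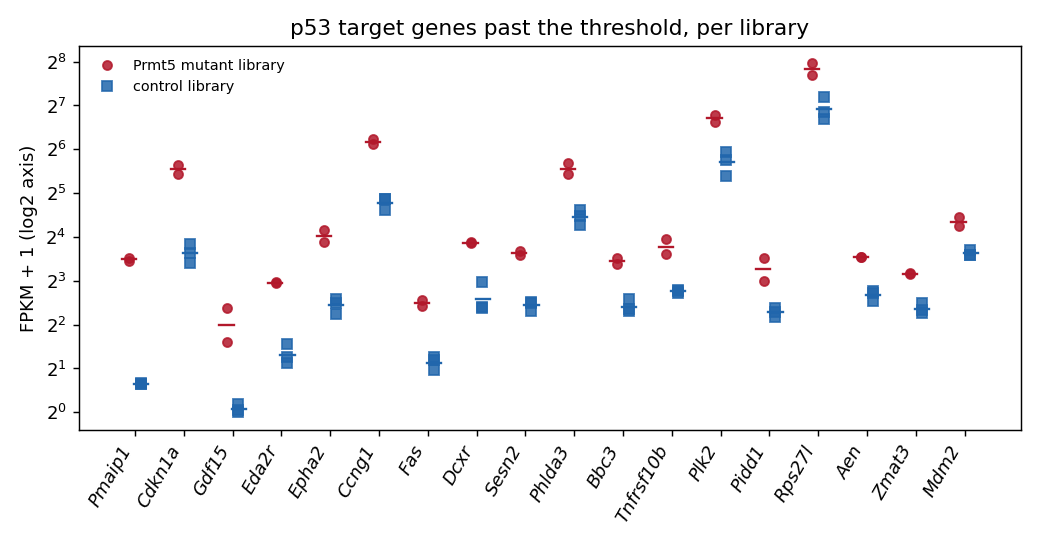
FPKM + 1 (vertical log2 axis) of the 18 p53 target genes past the threshold, in each of the 2 mutant libraries (circles) and 3 control libraries (squares), with lines at the group means of log2(FPKM + 1). For each gene both mutants lie above all 3 controls, as for Pmaip1, at 10.4 and 10.0 FPKM in the mutants and 0.556 to 0.602 FPKM in the controls.

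Some genes of the conducting airway epithelium were lower in the mutants. Of 6 secretory markers tested, 2 passed and both were lower, and all 6 were lower adjusted over the list alone. Aldh1a7, an aldehyde dehydrogenase gene, went from 55.5 ± 19.2 (SD, n = 3) to 9.50 ± 1.70 FPKM (SD, n = 2), and Muc1, a mucin gene, from 4.69 ± 2.24 to 0.72 ± 0.291 FPKM (adjusted p = 0.0077 and 0.0476). Scgb3a2, a secretoglobin gene, was at 4.40 and 7.62 FPKM in the mutants and 75.5, 21.6 and 22.3 FPKM in the controls (adjusted p = 0.0668). Lypd2 and Hp had log2 changes of -2.82 and -1.33 (adjusted p = 0.0516 and 0.0593). Cyp2f2, a cytochrome P450 gene of club cells, had 0 reads in the mutants and 731 in the controls, at least 144-fold lower, but its controls were at 17.2, 0.697 and 1.52 FPKM (adjusted p = 0.262). The median log2 change of the list was -2.21, or -2.36 with Cyp2f2 at its bound. Its camera adjusted p = 1.27e-05 was lost with an estimated correlation (adjusted p = 0.446).

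Multiciliated cell genes were mostly below the filter, with 9 tested of the 40 found in the table. Tppp3, a tubulin-binding protein gene, fell (log2 change -0.78, SE 0.14, adjusted p = 0.0421), and 2 genes were lower adjusted over the list alone. Ccno, which acts in the amplification of centrioles, was at 0.981 and 1.57 FPKM in the mutants and 9.27, 3.27 and 3.83 FPKM in the controls (adjusted p = 0.0926). Myb and Rfx3, transcription factor genes, had log2 changes of -0.66 and -0.40. Foxj1, the transcription factor of motile cilia, was at 0.702 and 0.463 FPKM in the mutants and 0.959, 0.491 and 0.377 FPKM in the controls, with 48 and 86 reads in all, and was not tested. Of the 31 genes not tested, the groups overlapped for 27. Both mutants lay below all 3 controls for Mcidas, Gmnc and Ak7, with 4, 1 and 1 reads against 135, 112 and 13, and above them for Drc1, with 24 reads against 23. The list's camera adjusted p = 0.0444 was lost with an estimated correlation (adjusted p = 0.446). It was 0.156 without mutant replicate 1, 0.0518 without control replicate 1 and 0.0576 without control replicate 2, and 0.626 with no filter, 0.0809 with quantile normalization and 0.0581 with TPM without Gm23935.

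Some neuroendocrine markers fell, with 3 of 11 lower and 6 lower adjusted over the list alone, and 10 lower and 1 higher in sign. Calca, Chga and Chgb did not pass, at log2 changes of 0.06, -0.32 and -0.22 (adjusted p = 0.937, 0.491 and 0.648). Uchl1, an ubiquitin hydrolase gene, and Nov, a secreted matrix protein gene, fell by 0.86 and 1.31 on the log2 scale (adjusted p = 0.0163 and 0.0479), while Ddc was at -0.47 (adjusted p = 0.115). The list's camera adjusted p = 9.12e-05 was lost with an estimated correlation (adjusted p = 0.446). Notch pathway genes were lower by camera (adjusted p = 0.0095, 0.0763 without mutant replicate 2 and 0.0658 with TPM), but not with an estimated correlation (adjusted p = 0.627), with 2 of 15 lower and 5 lower adjusted over the list alone. Hey1, a Notch target, fell by 0.97 and Lfng, a modifier of Notch receptors, by 0.71 (adjusted p = 0.0175 and 0.0383). Both lost the threshold with no filter, with TPM and with the male share as a covariate. Hes1 and Hey2 were at -0.46 and -0.80 (adjusted p = 0.0943 and 0.13).

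Epithelial genes as a whole did not pass. Of 26 pan-epithelial markers 1 passed, Foxa1, a forkhead factor gene, which fell from 20.1 ± 8.09 (SD, n = 3) to 6.48 ± 0.0727 FPKM (SD, n = 2; log2 change -1.43, adjusted p = 0.0419), and it was also the 1 marker lower adjusted over the list alone. Epcam and Cdh1, cell adhesion genes, had log2 changes of -0.92 and -0.46, Foxa2 and Spint2 of -0.92 and -0.68, and St14 of 0.88 (adjusted p = 0.181, 0.49, 0.0833, 0.126 and 0.0996). Nkx2-1, the lung lineage factor, was at 34.5 ± 2.37 FPKM (SD, n = 2) in the mutants and 34.6 ± 12.3 FPKM (SD, n = 3) in the controls. Control replicate 1 was the richest in epithelium, with Epcam at 124 FPKM against 66.5 and 51.4 FPKM in the other controls. The list's camera adjusted p was 0.0769, but 0.0173 without mutant replicate 2 and 1.66e-06 without control replicate 3. It also passed, lower, with median ratio scaling, quantile normalization and 4 other settings (adjusted p = 6.53e-16 to 0.0347). Shh, a signal of the epithelium and a gene that the design text names with Prmt5 in the mutant genotype, fell by 1.21 on the log2 scale (SE 0.22, adjusted p = 0.0416). Since Shh is part of that genotype, its fall cannot be read as an effect of the loss of Prmt5 alone. The labels give the controls as WT, so the same limit holds for every other difference between mutants and controls. Of 9 basal cell markers Ngfr fell (log2 change -0.70, adjusted p = 0.0313), also adjusted over the list alone, while Trp63, the basal cell factor, was at -0.71, Krt17 at -1.21, Itga6 at -0.26 and Snai2 at 0.72 (adjusted p = 0.386, 0.364, 0.381 and 0.201). Control replicate 1 stood apart for Trp63, at 4.91 against 1.24 and 1.55 FPKM in the other controls, and for Krt17, at 17.0 against 3.01 and 2.51 FPKM. Ngfr is also a gene of nerves and mesenchyme, and the basal list did not pass (camera adjusted p = 0.345).

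Some distal lung genes rose in the mutants, with 4 of 16 higher over all genes and 9 higher and 1 lower adjusted over the list alone. With the male share as a covariate 0 of the 4 stayed past the threshold (adjusted p = 0.13 to 0.197). Sftpa1, a surfactant protein gene, was 7.75-fold higher and Napsa, which encodes a protease that processes surfactant protein, 8.05-fold higher, both from low levels (3.42 and 1.80 FPKM in the mutants, adjusted p = 0.029 and 0.0297). The controls of Sftpa1 varied widely, at 0.468, 0.836 and 0.0192 FPKM. Slc34a2, a phosphate transporter gene of alveolar cells, had 364 reads in the mutants and 5 in the controls (log2 change 1.67, SE 0.24, adjusted p = 0.0195). Etv4, an FGF-induced factor of the branching tips, went from 4.38 ± 0.841 (SD, n = 3) to 10.3 ± 1.26 FPKM (SD, n = 2; log2 change 1.08, SE 0.16, adjusted p = 0.0228). Sftpc varied widely, at 34.4 and 46.7 FPKM in the mutants and 18.9, 56.2 and 4.85 FPKM in the controls (adjusted p = 0.507). Sox9, a factor of the tips and of cartilage, had a log2 change of 0.23 (adjusted p = 0.548). The list's camera adjusted p = 7.78e-08 was lost with an estimated correlation (adjusted p = 0.446).

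**Figure D2:**
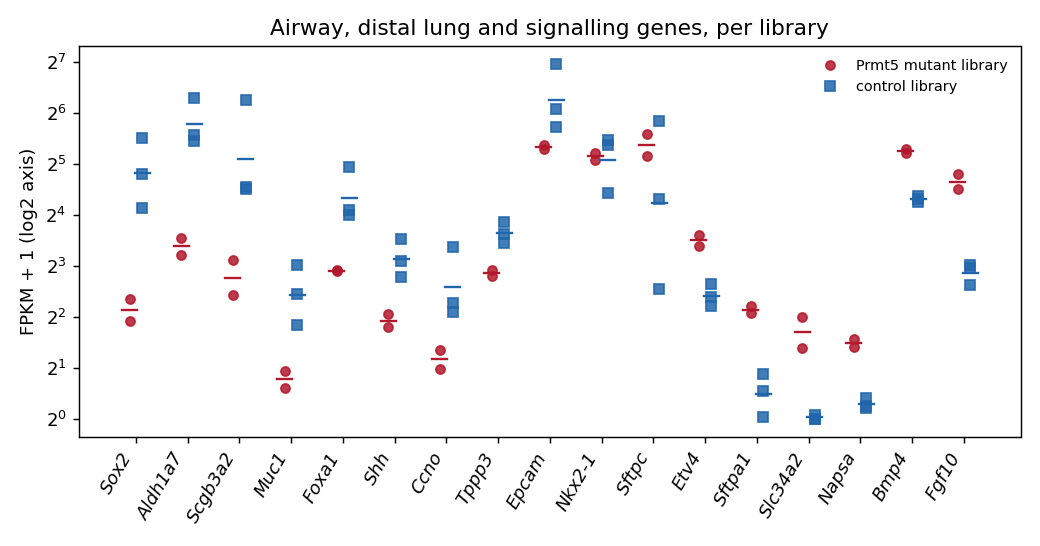
FPKM + 1 (vertical log2 axis) of airway, distal lung and signalling genes in each of the 2 mutant libraries (circles) and 3 control libraries (squares), with lines at the group means of log2(FPKM + 1). Sox2 lies at 4.10 and 2.76 FPKM in the mutants and at 16.5 to 44.3 FPKM in the controls, while Fgf10 lies at 26.9 and 21.6 against 5.14 to 7.11 FPKM, and the groups overlap for Nkx2-1 and Sftpc.

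Of 15 genes of FGF signalling, 4 were higher, and 5 adjusted over the list alone. With the male share as a covariate Etv4, Dusp6 and Bmp4 lost the threshold and Fgf10 kept it. The other 11 did not pass, at log2 changes of -0.50 for Spred3 to 0.92 for Etv5, with the feedback genes Spry1, Spry2 and Spry4 at 0.18, 0.10 and 0.13, and the median of the list was 0.18. Fgf10, the mesenchymal signal that drives branching, went from 6.32 ± 1.04 (SD, n = 3) to 24.2 ± 3.71 FPKM (SD, n = 2; log2 change 1.79, SE 0.16, adjusted p = 0.00641). Dusp6, a feedback inhibitor of the pathway, was 1.65-fold higher (adjusted p = 0.0293), and Etv4 and Bmp4 are members too. The list's camera adjusted p = 7.46e-06 was lost with an estimated correlation (adjusted p = 0.446). Bmp4 (chromosome 14, 46383520 to 46390669), a ligand made at the tips and in mesenchyme, went from 18.8 ± 0.844 (SD, n = 3) to 37.0 ± 1.49 FPKM (SD, n = 2; log2 change 0.94, SE 0.10, adjusted p = 0.00795). Of 23 BMP ligands, receptors and antagonists, Bmp4 rose and Chrd, an antagonist, fell by 1.00 on the log2 scale (adjusted p = 0.0394), with 1 higher and 7 lower adjusted over the list alone. Fst, another antagonist, and Bmp3 had log2 changes of -0.93 and -0.66 (adjusted p = 0.0516 and 0.0678), and the list did not pass (camera adjusted p = 0.0938). Of 10 BMP-SMAD target genes, Bambi, a decoy receptor gene, rose 2.02-fold (adjusted p = 0.0294), with 2 higher and 1 lower adjusted over the list alone. Id1 was at 75.1 ± 8.73 (SD, n = 2) against 83.2 ± 8.35 FPKM (SD, n = 3), and Id3 at 125 ± 19.4 against 120 ± 26.7 FPKM, both within the spread between replicates (adjusted p = 0.614 and 0.892). Id2, Id4 and Smad9 had log2 changes of 0.54, -0.60 and -0.23 (adjusted p = 0.1, 0.0736 and 0.479), and the list did not pass (camera adjusted p = 0.345). Its mean of 0.07 and camera's direction were up and its median of -0.03 down.

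Of 17 mesenchyme markers 4 passed and 13 did not. Tbx4 and Wnt2, genes of lung mesenchyme, were 2.05-fold and 2.76-fold higher along with Fgf10 (adjusted p = 0.0342 and 0.0485, the latter lost in 10 of 15 settings with all libraries), and Twist1 fell by 1.13 on the log2 scale (adjusted p = 0.0419). Adjusted over the list alone, 5 were higher and 1 lower, and the list did not pass (camera adjusted p = 0.176), with a mean of 0.17 and a median of -0.03, but was higher with the male share as a covariate (adjusted p = 0.00106). Mesothelium markers were higher by camera (adjusted p = 0.000573), but not with an estimated correlation (adjusted p = 0.446) or by fry (adjusted p = 0.16). There were 0 of 8 past the threshold by limma over all genes and 5 higher adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 with voom. Upk1b, Aldh1a2, Wt1 and Lrrn4 had log2 changes of 0.97, 1.34, 1.22 and 1.40 (adjusted p = 0.0516, 0.106, 0.147 and 0.178).

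Most skeletal muscle markers fell, and lists of other tissues around the trachea were lower by camera with most of their members short of the threshold. All of these lists were lost with an estimated correlation (adjusted p = 0.446). Of 7 skeletal muscle markers 6 were lower, and all 7 adjusted over the list alone. Myh3, the embryonic myosin heavy chain gene, went from 22.8 ± 8.60 (SD, n = 3) to 1.04 ± 0.443 FPKM (SD, n = 2; log2 change -3.49, SE 0.31, adjusted p = 0.00641). Acta1, Myog and Myod1 fell by 3.23, 2.67 and 2.31 on the log2 scale (adjusted p = 0.0107, 0.0077 and 0.00862). Outside the list, the muscle genes Mylpf, Mybph, Myl1, Atp2a1 and Tmem8c, which encodes a muscle cell fusion protein, fell by 2.02 to 3.38 (adjusted p = 0.00303 to 0.0355). Camera with its preset correlation gave the list an adjusted p = 1.65e-09. Cartilage markers had 4 of 13 lower and 5 adjusted over the list alone, with Col2a1, Col9a1, Col9a3 and Col11a1, collagen genes of cartilage, falling by 1.42, 1.65, 1.29 and 0.95 (adjusted p = 0.0178, 0.0293, 0.0353 and 0.0333). Neural and neural crest markers had 3 of 15 lower and 11 adjusted over the list alone, with Ret, Dbh and Tubb3, genes of neurons of the gut and airway wall, falling by 1.00, 1.09 and 0.82 (adjusted p = 0.0254, 0.0433 and 0.0485). All 3 lost the threshold with no filter, with TPM, with the replicate block and with the male share as a covariate. Gap43 was at -0.74 (adjusted p = 0.0517). Smooth muscle markers had 1 of 11 lower, Actg2, which fell by 1.89 (adjusted p = 0.0107), with 6 lower and 1 higher adjusted over the list alone. Cnn1, Myh11 and Mylk had log2 changes of -1.37, -2.02 and 0.45 (adjusted p = 0.0516, 0.0772 and 0.107). With its preset correlation, camera gave the cartilage, neural and smooth muscle lists adjusted p of 0.000884, 1.2e-07 and 0.00105.

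**Figure D3:**
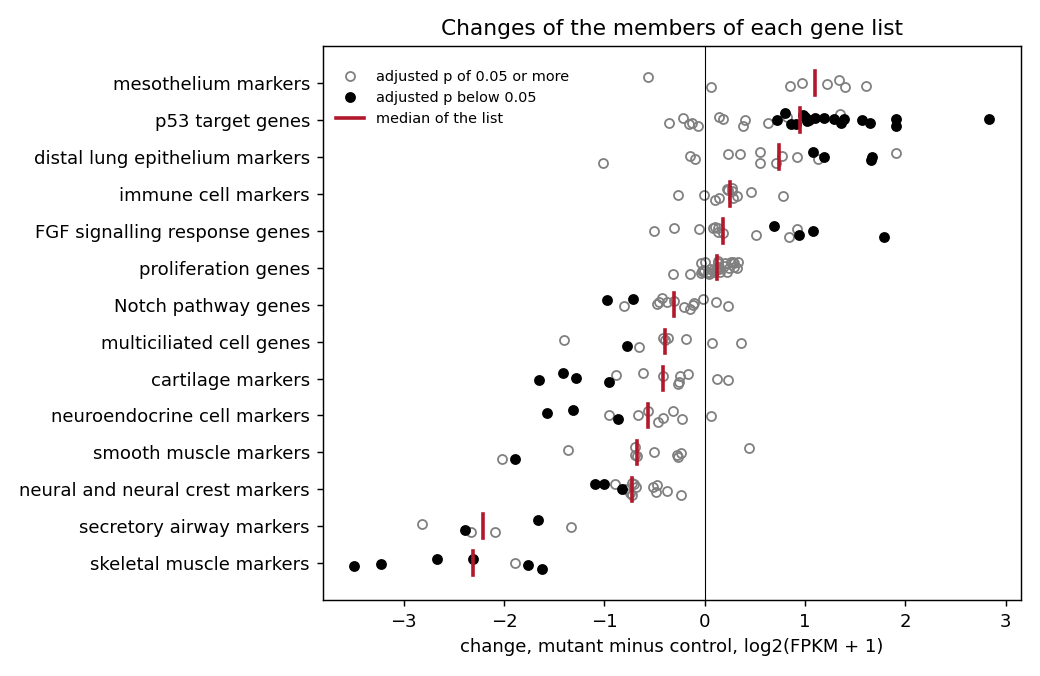
Log2 change, mutant minus control, on the log2(FPKM + 1) scale (horizontal axis) of each tested member of the 14 gene lists past camera's threshold with its preset correlation, filled where the gene's adjusted p was below 0.05, with a bar at the list's median. The medians run from -2.31 for skeletal muscle to 1.10 for mesothelium, and 0 of these lists passed with an estimated correlation.

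The proliferation and immune cell lists were higher by camera by small amounts, but not with an estimated correlation (adjusted p = 0.627 for both). Of 31 proliferation genes 0 passed by limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 with voom, and the median log2 change was 0.13. Gins2, Cdk1 and Pcna, which act in DNA replication and mitosis, had log2 changes of 0.28, 0.33 and 0.33 and Ccne2 of -0.31 (adjusted p = 0.222, 0.254, 0.276 and 0.217). The list's camera adjusted p was 0.00102, but 0.0965 without mutant replicate 2, 0.0771 without control replicate 3, 0.145 with TPM, 0.0864 with the replicate number as a block and 0.807 with the male share as a covariate. Of 12 immune cell markers 0 passed by limma, over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05 and 0 passed with voom, with Tyrobp, Fcer1g, C1qb and Mrc1, genes of macrophages, at log2 changes of 0.78, 0.32, 0.47 and 0.23. Their camera adjusted p was 0.00547, but 0.0579 without mutant replicate 1, 0.173 without control replicate 1 and 0.053 with the gene length trend removed. The other 9 lists, of Wnt, Hedgehog and PRMT genes, endothelial, erythroid, heart and liver markers, stress genes and sex-linked genes, did not pass (camera adjusted p = 0.0938 to 0.998), though Wnt2, Shh, Jun and Xist passed as single genes. Heart markers differed within the groups, with Myl7, an atrial myosin gene, at 98.2 and 286 FPKM in the mutants and 149, 147 and 623 FPKM in the controls.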

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

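Settings named here as added were chosen after the data were seen. Of the counts of changed genes, 303 as reported, the 69 with no filter (52 of them shared), the 67 with TPM (45 shared) and the 182 with a change of at least 1 on the log2 scale lay more than 1.5 times lower. So did the added covariate for male share, with 94 (60 shared), while voom on the recovered reads gave 600 (276 shared) and a mean of at least 50 reads 592 (264 shared), both also added. Leaving out 1 library gave 4 to 284 genes. The no-filter fit tests 19699 genes and leaving out a mutant leaves 1, and for the other settings the cause was not tested. Other settings gave 248 to 395 genes. Of the 63 genes of the naming rule past the threshold, 46 lost it with no filter, 38 with TPM, 34 with the male share, 13 with the replicate block and up to 11 of those tested with any other setting that kept all libraries. A minimum of 5 FPKM left 46 of them tested and a mean of at least 50 reads 56. Prmt5 stayed lower and short of the threshold throughout, at log2 changes of -0.18 to -0.86. Of the 14 lists past camera's threshold, 0 passed with an estimated correlation and 1 with fry's directional test, and 12 to 21 lists passed under the other settings. With the replicate number as a block 259 genes passed, 171 of them shared. The numbers were not shown to pair the samples, since the deviations of libraries with the same number correlated at -0.07 and 0.02 over 2 pairs only. Directions that turned were among values short of the threshold. With TPM, log2 changes were -0.50 for Id3, -0.50 for Nkx2-1, -0.32 for Sox9, -0.27 for Gins2, -0.24 for Cdk1, -0.25 for Pcna, -0.11 for Mylk, -0.20 for Fcer1g, -0.077 for C1qb, -0.29 for Mrc1 and -0.031 for Id2, all above the median of all genes, which was -0.59 with TPM. Nkx2-1 was at -0.27 with the replicate block, -0.0033 with TPM without Gm23935 and -0.72 with the male share, where Sftpc was at -0.53. Leaving out 1 library gave Id3 -0.12 to 0.23 and Nkx2-1 -0.27 to 0.25, and turned the basal list (camera adjusted p of 0.0763 to 0.968, the latter without mutant replicate 1). The BMP ligand list turned with a minimum of 5 FPKM (adjusted p = 0.753). The cause of these turns was not tested. The effect of depth was not tested on its own. In the simulated data 87 of 92 calls on unchanged genes had a mean under 50 reads, as had 39 of the 303 genes called here.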

Other observations

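The genes of the next 2 paragraphs, the test of the neighbours of Prmt5, and the tests of epithelial share, of surrounding tissue and of sex in the distal lung genes alone were chosen after their results were seen, and the male share and gene length fits after the data were seen.

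Outside the lists, single genes of other tissues changed too, and no group of them was tested. Tbx1, a pharyngeal factor, went from 15.1 ± 3.22 (SD, n = 3) to 3.36 ± 1.76 FPKM (SD, n = 2), and Six2, Foxc1 and Barx1, transcription factor genes of head and foregut mesenchyme, fell by 1.70, 1.09 and 1.28 on the log2 scale (limma adjusted p = 0.00644, 0.0355 and 0.00797). Chrna1 and Chrng, subunit genes of the muscle acetylcholine receptor, and Rapsn, which encodes a partner of it, fell by 1.43, 1.32 and 1.38 (adjusted p = 0.0163, 0.0178 and 0.0293). Gata5, a transcription factor of heart and foregut, was 3.50-fold higher, and Npnt and Itga8, a matrix ligand and the integrin that binds it, were 2.51-fold and 2.15-fold higher (adjusted p = 0.0452, 0.00641 and 0.0479).

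Of 17 Hox genes tested, Hoxb6 and Hoxb8 were called higher, though not with the male share as a covariate, and 12 were higher and 5 lower in sign. Hoxa6, Hoxb5 and Hoxb7 had log2 changes of 1.73, 1.37 and 1.16 (limma adjusted p = 0.0517, 0.06 and 0.0516), higher in 2 of 2 mutants than in all 3 controls. The 5 lower in sign were Hoxd9, Hoxa3, Hoxc4, Hoxa4 and Hoxa2, at -0.26, -0.21, -0.19, -0.15 and -0.08. Further genes known as p53 targets, Psrc1, Gtse1 and Zfp365, had log2 changes of 1.20, 0.95 and 1.27 (adjusted p = 0.00862, 0.0163 and 0.0107), while Trp53 itself was at 0.32 (adjusted p = 0.277). Bmp4 lies 8.12 Mb from Prmt5, but genes within 20 Mb of Prmt5 were not called more often than others, with 6 of 237 against 2.36% of the rest (Fisher's exact test, two-sided, p = 0.827).

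Some conducting airway genes were lower and some distal lung genes higher in the mutants. A lower share of epithelium in the mutant pieces is argued against as the whole cause for the secretory genes. It would lower secretory and pan-epithelial genes alike, and their median log2 changes differed by -1.71, secretory minus pan-epithelial. The basal, multiciliated and neuroendocrine lists had medians of -0.66, -0.395 and -0.57, near the pan-epithelial median of -0.50. For these lists a lower share of epithelium stays open. The sex of the embryos is argued against as the whole cause for the lower airway genes. With the male share in the model, the 11 called genes of the pattern kept a median of 93.5% of their change (SE 6.69, over genes). The median kept was 112.1% for the 7 lower airway genes and 85.7% for the 4 distal lung genes. These genes come from the same 5 libraries, and this SE does not measure the spread between libraries. The male share was 106.85% and 93.15% in the mutants and 78.41%, 61.83% and 15.65% in the controls, so it went in part with genotype. Only 4 of the 11 stayed past the threshold, as the median SE rose from 0.237 to 0.328. For the distal lung genes sex stays open, since 0 of the 4 called genes, Slc34a2, Etv4, Sftpa1 and Napsa, stayed past it (adjusted p = 0.13 to 0.197). Their median change went from 1.425 (median SE 0.215) to 1.161 (median SE 0.339), and Sftpc, not called before, turned to -0.53. Pieces with less trachea, oesophagus and body wall may account for the lower conducting airway genes. Of the lists of such tissues, 4 of 4 were lower by camera with its preset correlation. This did not test the rise of the distal lung genes and decides nothing for them. With an estimated correlation none of the 4 passed (adjusted p = 0.446), nor did any by fry's directional test (adjusted p = 0.0658 to 0.116). A change of airway cell fate with genotype is a hypothesis that was not tested and stays open beside that.

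Of 30 p53 target genes tested, 18 were higher in the mutants and 12 were not past the threshold, and the list was higher by camera with its preset correlation but not with an estimated one (adjusted p = 0.34). The sex of the embryos is argued against as the whole cause, though the male share went in part with genotype. With the male share in the model, the 18 called members kept a median of 98.4% of their change (SE 3.35). The SEs of such percentages are over genes of the same libraries and do not measure the spread between libraries. Only 6 of the 18 stayed past the threshold, with a median change of 1.147 before and 1.145 after, as the median SE rose from 0.143 to 0.231. A trend with gene length is argued against too, with 104.8% once it was removed (SE 1.37) and 17 of the 18 past the threshold. The balance of tissues cannot be told apart from genotype, since a score of it correlated with genotype at -0.925. With that score in the model the members kept 100.6% of their change (SE 8.67). By the rule set for this test, so high a correlation makes it void, and the value decides nothing. A p53 response to the loss of Prmt5 is a hypothesis that stays open. It cannot be told apart from an effect of the Shh part of the mutant genotype.

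Ribosomal protein genes were higher in sign in the mutants, at 77 of 77 with a median log2 change of 0.44, although limma called only 1, Rpl39, past the threshold. TPM turned the median to -0.13, which was 0.46 above the median of all genes, and quantile normalization, which gave 0.20, kept 69 of 77 higher. Gene length is argued against, since the median lay 0.321 above the upper bound of 10000 random lists matched on length and level (-0.01 to 0.12). A single scaling factor per library is argued against as well. It would move all genes alike, and the median log2 change of all genes was -0.06. Median ratio scaling kept 116.8% of the change, but this follows from that median and adds no further support. Quantile normalization lowered the median of the ribosomal protein genes from 0.44 to 0.20, so the size of the change depends on the normalization. Tissue balance was not tested here and stays open, and so does a change with genotype.

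Chance was weighed for the 303 genes with the 10 splits of the 5 libraries into 2 and 3, which are too few for a share under 0.05. The real split was the 1 split with as many genes, and the highest of the others gave 0 genes with limma.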
